A study of Metallibacterium scheffleri with 2 samples.

How the data were processed

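RNA from Metallibacterium scheffleri strain DKE6, an acid-tolerant bacterium, was sequenced in 2 samples of a single condition. Per the labels' protocols, cells grew at 30 °C with shaking at 150 rpm in 21 mL of a mineral medium that held 10 mg/L casitone (a peptide digest of casein) and was buffered to pH 4.5. The sample titles give pH 4.84, and the labels do not say to what that value refers. Each sample pooled 3 cultures harvested in exponential growth. Per the labels' protocols, RNA was depleted of genomic DNA and of ribosomal RNA, and strand-specific libraries were made from 50 ng and run together in 1 lane. The labels describe both samples as independent biological replicates, and each is 1 replicate here. There is 1 group, so no test between conditions exists.

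The authors deposited raw read counts per feature for each sample. Per the submitters' processing notes, CASAVA 1.8.1, Bowtie2, SAMtools, HTSeq and DESeq2 were used, and the notes as held here give them no role or order. The last 5 lines of each deposited count file carry the names that HTSeq gives to reads without a feature. The genome build, the strand setting, the counting mode and the minimum alignment quality are not given in the sources used here. Because the strand setting is not given, it could not be checked that the counted reads run in the sense direction of each feature.

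Each of the 3445 features is named by a sequence number from 01 to 05, a start and an end, and some names carry "comp.", read here as the complement strand. Positions are printed as these names give them. All feature lengths were multiples of 3 (range 114 to 8616 bp, median 792 bp), so they are coding lengths and no ribosomal or transfer RNA feature is listed. The files pair no feature with a gene name or product, and no genome or annotation was used. Before the data were examined, 37 lists of genes by product name had been fixed. None could be run without product names, and the features are therefore described by position. The rule for named features, also fixed before the data were examined, took the 20 features with the highest mean TPM and, of the features that differed between the samples with at least 50 reads in total, those with the most extreme ratios. The rule asked for 3 in each direction, and 2 are printed because the identifiers carry no names. All statements on sequences, regions, silent runs, stretches of neighbours and copies were chosen after their values were seen.

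Reads without a feature stayed out of library sizes and tests. Of all reads, 96.9% in replicate 1 and 97.0% in replicate 2 fell below the counting tool's minimum alignment quality. Another 1.59% and 1.48% lay outside every feature, 0.14% in both did not align, and 1.38% in both were counted in features. In both replicates 0 reads were classed as not uniquely aligned, so the low-quality class may hold reads that fit several places. Replicate 1 kept 697852 reads in features and replicate 2 kept 1025384. A count of 0 allows up to 3 reads, which is 4.30 CPM (reads scaled to the library total) in replicate 1 and 2.93 CPM in replicate 2. Reads carry no molecular identifiers, so floors cover counting error only. The median feature held 28 reads in replicate 1 and 40 in replicate 2, and the lowest levels therefore rest on few reads. In the deposited counts 715 neighbouring features overlap, by a median of 4 bp and at most 126 bp, while both files list 0 ambiguous reads. How reads in the overlaps were assigned is not given in the sources used here.

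TPM was computed from the deposited counts and the coding lengths with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Logarithms used a pseudocount of 0.5 reads. A feature was called detected with at least 10 reads in each sample. Shares of features carry 95% Wilson intervals. These treat features as independent draws, and cover neither the counting of reads nor the spread between cultures. Library scaling (TMM) and the common dispersion of the pair, fitted as 1 group, came from edgeR 4.0.16 in R 4.3.3. Whether the samples were a single library deposited under both names was checked by a chi-square test of their counts over features. Each feature was compared between the samples with a two-sided exact binomial test against the TMM-scaled library sizes, with Benjamini-Hochberg adjustment over 3445 features, and called at an adjusted p under 0.05 and a change of at least 2-fold. This compares 2 libraries, not conditions, and covers counting noise only. On simulated libraries of 3445 features, the test recovered 96 of 100 features changed 3-fold and 97 of 100 changed 4-fold, and called 6 of 3245 unchanged features. The simulated libraries held counting noise only, and changes were planted only in features with at least 50 reads in total. These rates therefore cover neither the wider spread between the real libraries nor features with few reads.

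A silent run was a stretch of neighbouring features with at most 2 reads each over both samples. A feature was called copied where it and a neighbour recur elsewhere with the same lengths, gap and relative strands. The search was run on 612 features that included 12 exact copies planted among features of sequence 02, and found all 12. An exact match cannot be missed by this rule, so the run checked the code only. How often lengths and gaps match by coincidence was not measured. Alternatives were other read minimums, DESeq2 1.42.0 size factors and dispersion, total-count scaling, an edgeR exact test, ranking by reads in place of TPM, and each replicate alone.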

Results

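The series measured the transcriptome of Metallibacterium scheffleri DKE6 in exponential growth under 1 condition, in 2 replicates that each pooled 3 cultures. Its title sets the transcriptome beside the genome's metabolic potential, so the comparisons possible here lie between features within that condition and between the replicates. Replicate 1 had 697852 reads in the 3445 coding features and replicate 2 had 1025384, out of 50665041 and 74086396 reads. The files give each feature a position on 1 of 5 sequences and no gene name.

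Of the 3445 coding features, 2292 were detected with at least 10 reads in each replicate, which is 66.5% (95% Wilson interval 64.9 to 68.1%). Another 465 features, 13.5% (12.4 to 14.7%), had 0 reads in both replicates. The silent features were unevenly spread. On the 2 large sequences most features were detected, 809 of 1079 on sequence 01 and 1449 of 1983 on sequence 02. On sequence 05, 19 of 37 features were detected. Sequence 03 had 1 detected feature of 30, and sequence 04 had 14 of 316, or 4.43% (2.66 to 7.30%). Sequences 01 and 02 together held 99.3% of the reads of both replicates, and sequence 04 held 0.51% in replicate 1 and 0.56% in replicate 2.

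Sequence 04 was divided at one place. Its first 24 features, which end at position 37865, held 3561 reads in replicate 1 and 5763 in replicate 2, and 14 of them were detected. The next 292 features, from position 38584 to 381388, held 1 read in each replicate, both in the first of them. The other 291 features had 0 reads over 262.4 kb of coding length. With 3 reads per library as the limit of a count of 0 over all 291, their level was at most 0.0115 reads per kb. Sequences 01 and 02 averaged 235 reads per kb in replicate 1 and 345.1 in replicate 2. In counted reads, these 291 features therefore lay at least 20558-fold lower in replicate 1 and at least 30186-fold lower in replicate 2. Reads below the quality minimum were assigned to no feature, so these limits do not cover them. The block made up 89.9% of sequence 04 up to the end of its last feature. The next longest run of silent features anywhere held 18, on sequence 03 from 10923 to 24210. In all, 13 runs of 5 or more silent features were found, and several lay at the ends of sequences 01 and 02. Part of the features in those end runs recur elsewhere in the feature list with the same lengths and spacing. So do 8 of the 18 in the run on sequence 03, and part of its other run and of the run on sequence 05. The counts of all these features are uncertain where the counting tool could not place reads on 1 copy.

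**Figure D1:**
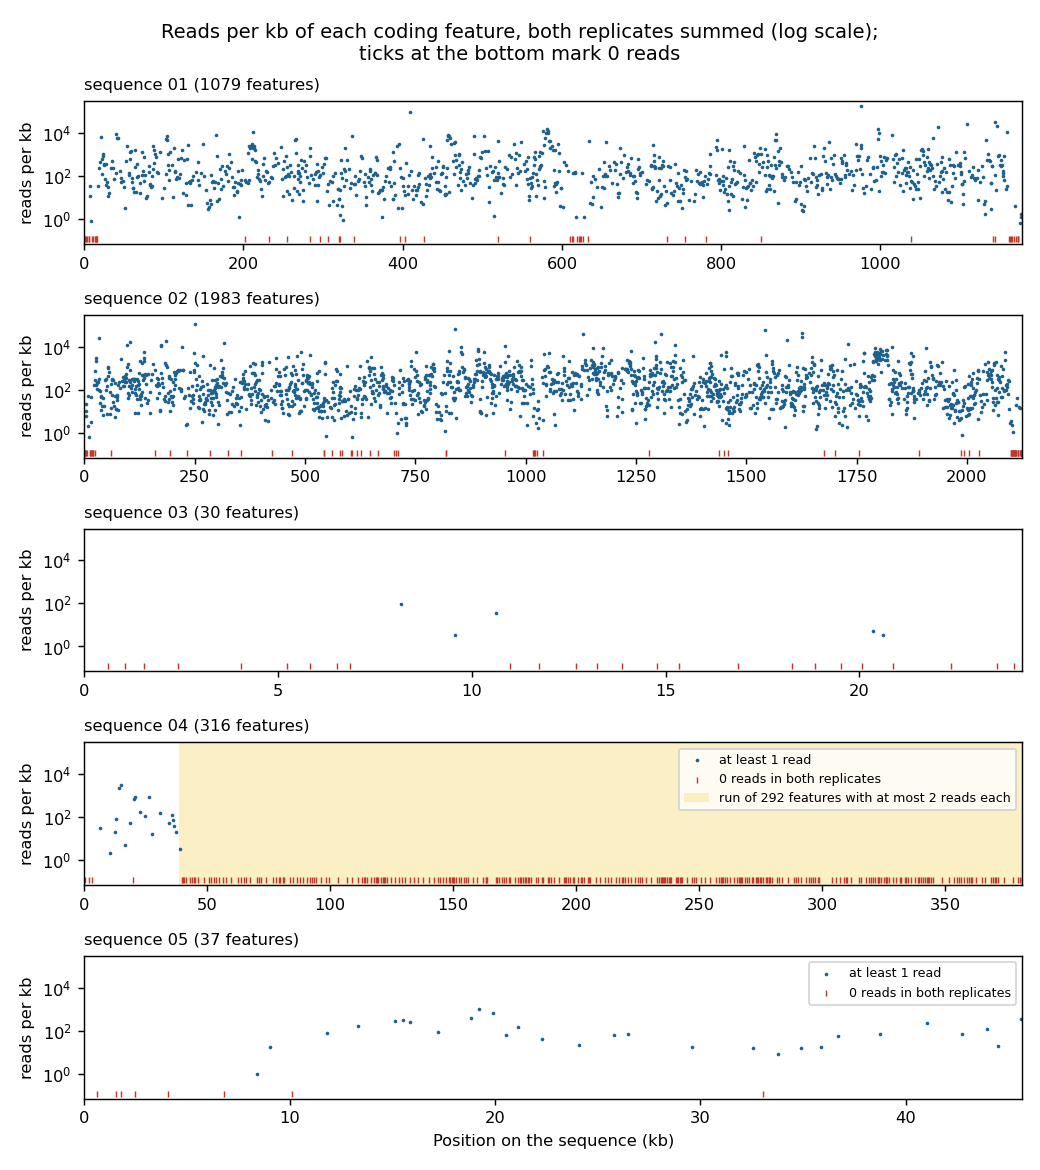
Each point is 1 coding feature, placed by its position on the sequence (kb, horizontal axis) and by its reads per kb of coding length with both replicates summed (vertical axis, log scale). Ticks at the bottom mark features with 0 reads in both replicates, and the shaded part of sequence 04 is the run of 292 features that held 2 reads in all, while the 24 features before it held 3561 and 5763 reads in the 2 replicates.

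Transcript levels were concentrated in few features. The 10 features with most reads held 21.3% ± 0.11 (SD, n = 2) of the reads in features and the 100 with most reads held 52.6% ± 0.89 (SD, n = 2). The 20 features with the highest TPM ranged from 5985 to 67340 TPM, against a median of 35.7 TPM over all features. Of these 20, 7 lay on sequence 01 and 13 on sequence 02, and 17 were shorter than 600 bp, against 37.5% of all features. TPM divides reads by length, so it ranks short features higher than reads alone do. When features were ranked by reads in place of TPM, 10 of the 20 stayed among the first 20.

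The most abundant feature was a 342-bp coding sequence on the complement strand of sequence 01, at 975864 to 976205, with 67340 ± 12030 TPM (SD, n = 2). A 570-bp feature on sequence 02, at 250501 to 251070, followed with 45067 ± 2430 TPM. A 417-bp feature on sequence 01, at 409324 to 409740, had 36222 ± 789 TPM. A pair of features of the same length, 210 bp, came next on sequence 02, at 839484 to 839693 with 24504 ± 4675 TPM and at 1543259 to 1543468 with 22733 ± 5753 TPM. Neighbouring features on the complement strand of sequence 02 ranked 6 and 10. The 735-bp feature at 1625862 to 1626596 had 18257 ± 2610 TPM and the 297-bp feature at 1625545 to 1625841 had 11511 ± 2070 TPM. The feature with most reads in replicate 1 and in the sum of both, with 38824 in replicate 1 and 39224 in replicate 2, was the 2982-bp feature on sequence 01 at 1107471 to 1110452. It ranked 11 by TPM, with 11070 ± 3371 TPM. None of these 20 features differed 2-fold between the replicates, and their log2 ratios of replicate 2 over replicate 1 lay between −0.47 and 0.68.

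High levels also occurred in long stretches of neighbouring features. The highest median over 20 neighbouring features was on sequence 02, from 1799403 to 1820079, with 1589 TPM. The next, with 1503 TPM, adjoined it from 1789203 to 1799391. Together they formed 40 features, all on the complement strand and all detected, with a median of 1586 TPM in replicate 1 and 1486 in replicate 2. They held 6.41% and 6.42% of the reads. Another stretch, on sequence 01 from 575331 to 592114, had a median of 926 TPM over 20 features on both strands, of which 15 were detected. This stretch held 3.86% of the reads in replicate 1 and 5.31% in replicate 2. Within it, 3 features between 578909 and 589643 were called higher in replicate 2. None of 1000 shuffles of the levels among features gave a 20-feature median above 458.8 TPM. The shuffles mixed levels across all sequences and broke the shared levels of close neighbours. They therefore show only that levels are grouped, not that these stretches exceed what neighbours in 1 transcription unit would give. With stretches of 10 features the highest median was instead on sequence 01, from 575331 to 583216, with 2929 TPM.

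The labels give the samples as 2 replicates, and they ranked the features alike. Across the 2980 features with a read, the log2 CPM values (reads scaled to the library total) correlated with Pearson's r = 0.970, and Spearman's rho was 0.985. These are correlations across features within 1 condition, and features are not independent replicates. The chi-square statistic of the counts was 25483 with 2979 degrees of freedom, 8.55 per degree of freedom, which is more than sampling noise gives for a single library deposited under both names. The common biological coefficient of variation was 0.137 from edgeR and 0.258 from the fitted dispersion of DESeq2. The fitted value was taken after the median gene-wise value of DESeq2 was seen to be 0.0001. Each library pooled 3 cultures, so these values describe the spread between 2 pools, not between single cultures. Of the 2292 detected features, 97.9% lay within 2-fold between the replicates after TMM scaling.

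By the exact binomial test, 29 features were higher and 6 lower in replicate 2. Among those with at least 50 reads in total, the 2 most extreme in each direction were a 462-bp feature on the complement strand of sequence 02 at 896064 to 896525, with 44 and 251 reads (log2 ratio 2.01, Benjamini-Hochberg adjusted p = 3.4e-21, exact binomial test), a 309-bp feature on sequence 02 at 1938850 to 1939158, with 8 and 44 reads (log2 ratio 1.90, adjusted p = 0.0014, exact binomial test), a 510-bp feature on the complement strand of sequence 01 at 90673 to 91182, with 49 and 28 reads (log2 ratio −1.28, adjusted p = 0.0024, exact binomial test), and a 627-bp feature on the complement strand of sequence 02 at 1376547 to 1377173, with 40 and 24 reads (log2 ratio −1.21, adjusted p = 0.015, exact binomial test). With total-count scaling in place of TMM the split was 27 higher and 12 lower. When the spread of the pair itself was put into an edgeR exact test, 17 features were called higher and 0 lower, and 102 features had an unadjusted p under 0.05.

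The features higher in replicate 2 were grouped along the sequences. Of the 29, 12 lay on sequence 02 between 894573 and 946230, 3 on sequence 01 between 578909 and 589643, and 3 neighbours on sequence 01 between 973235 and 975803. No feature in these regions was called lower. Up to 6 fell within 20 kb, and none of 1000 random draws of as many features reached more than 4. Neighbours in 1 transcription unit are not independent, so this shows grouping only. Within the region on sequence 02, 40 features had at least 50 reads. Their median log2 ratio was 0.38, their range was −0.61 to 2.01, and 10 of them lay below 0.

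**Figure D2:**
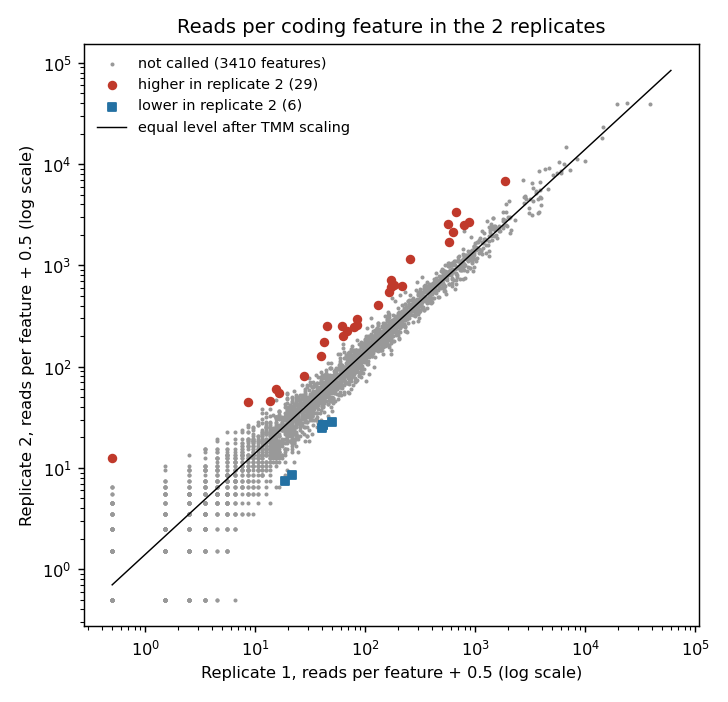
Each point is 1 of the 3445 coding features, with its reads in replicate 1 (horizontal axis) and in replicate 2 (vertical axis), both plus 0.5 and on log scales; the line marks equal levels after TMM scaling. The 29 features called higher in replicate 2 lie above the line and the 6 called lower lie below it.

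**Figure D3:**
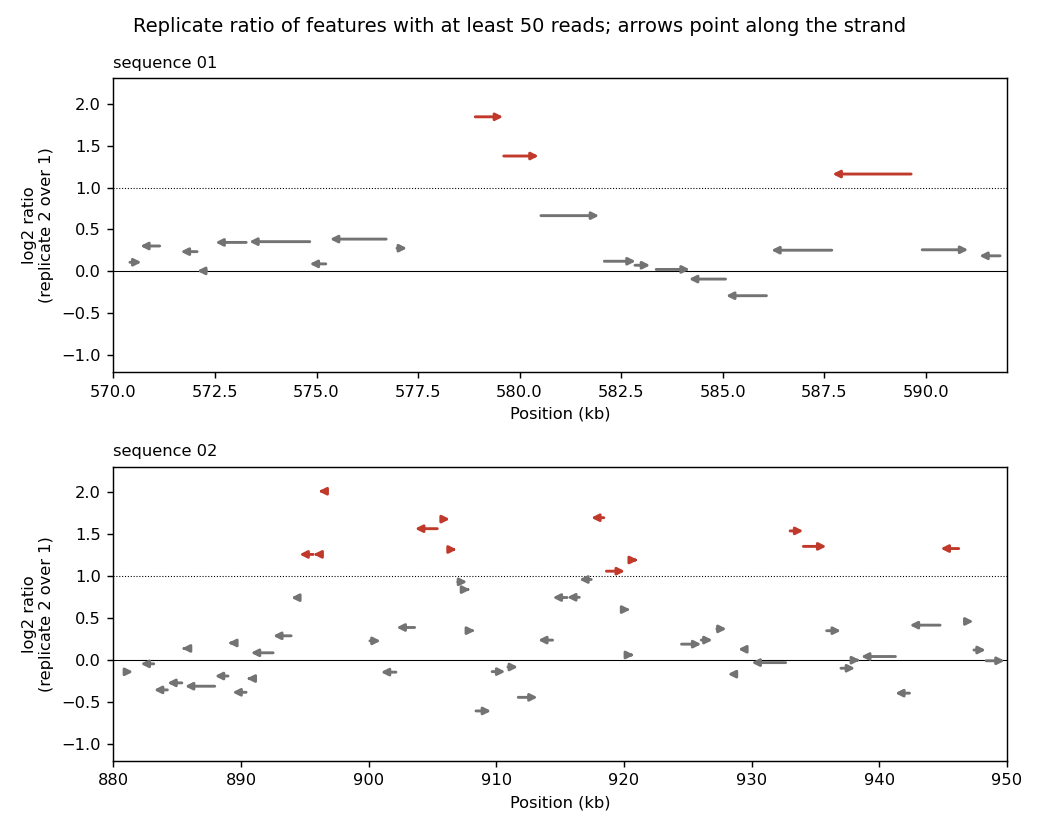
Each arrow is 1 feature with at least 50 reads, drawn to scale along its strand (position in kb, horizontal axis) at its TMM-scaled log2 ratio of replicate 2 over replicate 1 (vertical axis), for parts of sequences 01 and 02. Called features are in red, the dotted line marks a 2-fold ratio, and features near 0 or below it stand between the called ones.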

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

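All tests in this part were chosen after the results were seen. The read classes outside the features are reported because they hold far more reads than a count of 0 allows and enter no comparison. Reads placed outside every feature numbered 803944 in replicate 1 and 1095857 in replicate 2. Reads below the counting tool's quality minimum numbered 49092149 and 71865041, and reads that did not align numbered 71096 and 100114.

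Reads outside features outnumbered reads inside them, by 1.15 to 1 in replicate 1 and 1.07 to 1 in replicate 2, although features cover all but 12.3% of the sequence up to the last feature of each. One candidate explanation is RNA genes and transcript ends, since only coding features are listed. Another is counting on the opposite strand, since the strand setting is not given. Pairs of neighbours less than 50 bp apart were compared where each feature had at least 20 reads over both replicates. Their levels correlated more strongly on 1 strand than on opposite strands, by 0.568 in Pearson's r, but reads leaking from the sense strand would keep that order too. Among these pairs on opposite strands, r was 0.405 over the 23 that overlap and 0.026 over the 111 others. The files do not separate these explanations, and no biological explanation was tested.

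Outside sequence 04, 96 features recur as copies in length, spacing and relative strand. They stand in matched segments of neighbours and are not independent, which their interval does not take into account. Of these 96, 58 had 0 reads, or 60.4% (95% Wilson interval 50.4 to 69.6%), against 3.69% (3.08 to 4.43%) of the 3033 others. For part of them this is consistent with reads of repeats being lost below the quality minimum, while the 112 features at 0 reads without a copied neighbour stay open: 18 of them have a length that no other feature at 0 reads has, and the rest could be single copies. Reads were also placed on copies, with 707 and 744 reads on 1 pair of segments of sequence 01, and 0 reads on a segment of sequence 01 against 489 on its counterpart on sequence 05, so equal lengths and spacing do not show equal sequence. In the block of 292 on sequence 04, 0 features recur together with a neighbour, and 131 of its 291 features at 0 reads have a length that no other feature at 0 reads has. Only 18 of the 291 have a length that no other feature has, with or without reads. The 131 argue against full-length copies that all lie at 0 reads among the listed features as the whole cause. Where a counterpart may hold reads, length alone speaks against a copy only for the 18. Copies of other lengths or outside the features were not examined. Low depth is also argued against, since the poorest stretch of 292 features on sequences 01 and 02 held 62286 reads against 2 in the block. Whether the block was absent from these cultures, present and not transcribed, or transcribed with its reads lost below the quality minimum stays open. Each could give 291 features at 0 reads. The limit of 0.0115 reads per kb over those 291 covers counted reads only.

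For the features higher in replicate 2, extra copies of the whole region on sequence 02 would raise its features alike, but 25% of those with at least 50 reads lay below 0. That argues against a raise of 2-fold over the whole region. A smaller raise of the region stays open, since its median log2 ratio was 0.38 and the ratios of all detected features had an SD of 0.37. A uniform difference along transcripts throughout the library, large enough for a 2-fold change, would show in all 122 transcription units, where the log2 ratio of the first member exceeded that of the last by a median of 0.078 (interquartile range −0.157 to 0.326). A smaller difference of that kind stays open: the first member was the higher in 74 of the 122, or 60.7% (exact two-sided binomial p = 0.023). Among the 113 without a differing feature, the share was nearly the same, with 67 or 59.3% (p = 0.059 by the same exact test). A difference between the pooled cultures stays open as untested, since the design holds no second condition, and 1 pair of libraries does not separate it from a difference in preparation.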

How the results depend on the processing

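Of 92 values recomputed under an alternative for 36 results, 44 lay within 1 SD of the mean by construction, since they are TPM values and read shares of 1 replicate of 2. Of the other 48, 35 stayed within the margin set for that kind of result, 13 moved and 0 reversed. The margins differ between kinds of result, so these counts do not measure 1 common tolerance. A reversal could be scored only for the difference in neighbour correlation and the differences along units. A minimum of 100 reads left 953 detected features in all and 6 on sequence 04. Pearson's r between replicates was 0.984 over features with at least 10 reads in each. The DESeq2 fitted dispersion gave a coefficient of variation of 0.258 against 0.137 from edgeR. It was taken after the median gene-wise value was seen to be 0.0001, with 65.2% of features at the lower bound. The edgeR exact test called 17 features in all, 17 higher and 0 lower in replicate 2, because it adds the spread between the libraries. Total-count scaling called 12 features lower. Without the feature with most reads the first 100 features held 50.4% of reads. Ranking by reads kept 10 of the 20 features with the highest TPM. Stretches of 10 features gave a highest median of 2929 TPM, on sequence 01. With runs of 3 features as the rule for copies, 79.4% had 0 reads, or 74.4% on lengths alone. The cause of the other changes was not tested.

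Among the other 48, leaving out each replicate moved none of the results it was run for beyond the margin set for that result. The 37 product lists, their alternatives and the alternative with RNA genes were not run, since the files hold neither products nor RNA features. The agreement, spread, differing features and unit order need both libraries. No paired analysis was possible because there is 1 group. Depth limits the low features: the median feature held 28 reads in replicate 1. The settings for sequence 04, stretches, copies, neighbours and units were chosen after seeing the data.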

Other observations

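All tests in this part were chosen after the results were seen, as were the regions named. Neighbouring features shared levels where they lay close together on 1 strand. Only pairs in which each feature had at least 20 reads over both replicates were used. Among 814 neighbours less than 50 bp apart on the same strand, the log2 TPM correlated with Pearson's r = 0.678 and Spearman's rho = 0.627 across pairs. Among 134 such neighbours on opposite strands, r was 0.11 and rho 0.089, with r = 0.405 over the 23 pairs that overlap and 0.026 over the other 111. The difference of 0.568 was larger than in any of 10000 permutations of the strand relation (two-sided permutation p = 0.0001, the smallest they can give). On the same strand, r was 0.353 over 481 pairs 50 to 200 bp apart and 0.111 over 156 pairs 200 to 1000 bp apart. The pairs are not independent, since each feature enters up to 2 of them.

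Copied features stood in segments, of which the longest joins 7 features of sequence 01 from 8851 to 16365, with 0 reads, to 7 of sequence 02 from 2116624 to 2124138, with 52 reads. The order of the ratio between the replicates was examined along transcription units, defined here as features on 1 strand with gaps under 50 bp. Of the units with at least 3 members of 50 or more reads, 7 held a feature higher in replicate 2. The first member in the direction of the strand had a higher ratio than the last in 6 of these 7 (exact two-sided binomial p = 0.12), with a median difference of 1.46 on the log2 scale, a size that choosing units for a called feature raises. By a second summary, the slope of the ratio along the unit, 7 of 7 fell; both summaries were computed, and only the first was tested. The unit on sequence 02 from 882124 to 896525, with the largest difference of the 7, went from a log2 ratio of 2.01 at its first member to −0.04 at its last. Over all 122 units the median difference was 0.078, and the slope fell in 70. A hypothesis is that the 7 units were being switched on in replicate 2 near the time of harvest, so that their early parts may have risen more. The exact test does not decide it: the units are few, 6 of them lie close together on sequence 02, and there is 1 pair of libraries.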
